A study of Homo sapiens with 18 samples.

How the data were processed

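The series describes m6A immunoprecipitation sequencing of the human melanoma cell line MEL624 in a control line that carries a random sgRNA and in 2 clonal PCIF1 knockout lines, KO1 and KO2. It lists 18 libraries, 9 of input mRNA and 9 of m6A-immunoprecipitated mRNA, with 3 replicates per line that the series design calls biological. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was purified with magnetic beads in repeated rounds, and libraries were made with a directional kit. The submitters state an average of 20000000 reads per sample. The 9 m6A libraries were not analysed here, because no per-gene values of them were used.

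The deposited table holds log2 TPM (transcripts per 1e+06) values of 15258 genes, named by Ensembl identifiers, in 9 columns that match the input libraries by name. Per the submitters' processing notes, HISAT2 2.0.4, SAMtools 1.7, deepTools 3.0.2, featureCounts, R 3.3.3 and edgeR 3.12.1 were used with genome build hg38. The role of each tool, the gene annotation, the strand setting of the counting and the gene filter are not given in the sources used here. The deposited log2 values hold no 0 and no missing value, and 2 to the power of each column sums to 1e+06, so TPM was scaled over the listed genes. Genes without reads sit at a floor set by a small prior count that had been added before the logarithm. Log2 fold changes are on this scale, and those of genes near the floor depend on the prior.

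Whole reads per gene could be recovered from the steps between low values for 100% of genes (tolerance 1e-06 reads, largest distance 7.1e-09). They gave between 7848089 and 11393206 reads per library, 84602764 in all, below the stated average, which need not count the same reads. A limit of 3 reads is 0.263 reads per 1e+06 reads in the deepest and 0.382 in the shallowest library. For genes with 0 reads in a line, a bound was computed against 3 reads over the line's 3 libraries, and for 1 to 3 reads the ratio of read rates was given with an exact 95% counting interval. These cover counting error only, since reads without molecular identifiers are not independent molecules. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom 1.22 to 3.71 over genes with at least 20 reads), so no library was counted as a copy of another.

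The design was fixed before the data were examined. The main test was limma-trend (limma 3.58.1 in R 4.3.3) on the deposited log2 TPM values, with 1 mean per line over all 9 libraries, 6 residual degrees of freedom, and Benjamini-Hochberg adjustment over the 14512 genes with a mean of at least 1 TPM. Contrasts were KO1 against control, KO2 against control, KO2 against KO1 and the mean of both clones against control, and a gene was called at a two-sided adjusted p under 0.05. With 1 control line and 2 clones, p-values measure the spread between libraries of a line and not between independently edited lines. The value of PCIF1 was also compared by an exact two-sided permutation test, which cannot go below 0.1 for 3 against 3. Overlap between clones was set against 50 simulations of unchanged groups that share the control libraries, and against the product of the list sizes over the number of genes.

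Gene lists were fixed before the data were examined: 30 lists of pathways, complexes and markers of other cell types, of which 26 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast, again with an estimated correlation, and with fry. The named genes followed a rule fixed at the same time. It took PCIF1, the 8 highest and 8 lowest genes by mean fold change among those called in both clones with no overlap between knockout and control libraries, and for each clone the 4 highest and 4 lowest among genes also called between the clones. From each list it took up to 4 members with the largest change in both clones, else in 1 clone, else the most abundant. Values of many genes that the rule took are not reported here. Symbols, coordinates and start bases came from GENCODE 44 on hg38, which held 15138 of the 15258 identifiers, and 120 had no match. Start bases were taken at the most upstream annotated start and, as an alternative, at the start of the canonical transcript.

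Alternatives were log2(TPM + 1) and log2(TPM + 5) from recovered TPM, no filter and a mean of at least 5 TPM, median centring, quantile normalization, no variance trend, a fit of only the 2 lines compared, the replicate letter as a block, and leaving out each library in turn. Chosen after seeing the data were limma-voom on the recovered reads, a trend on GC content and log2 length subtracted from each library (for the 99.2% of genes with both values), and a running median of 51 neighbouring tested genes subtracted from each library. Windows of 25 neighbouring genes, stretches of at least 2 windows beyond 0.25, and gene families were also chosen after seeing the data, with 1000 random gene orders as background.

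The tests were run first on simulated data with changes at 200 genes in KO1. These were drawn from genes with a mean above 20 reads per library, so recovery among lower genes was not measured. Of 50 genes changed 1.5-fold, 76% were recovered in KO1 against control, and 96%, 100% and 100% at 2-fold, 4-fold and 8-fold. Calls among unchanged genes were 6 of 14312 in simulated KO1 against control, 0 of 14512 in simulated KO2 against control and 12 of 14312 in simulated KO2 against KO1. Camera called 0 of 20 random lists, but the genes were simulated independently, so false calls of lists with correlated members were not tested. Other software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.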

Results

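Messenger RNA of MEL624 cells, an established human melanoma line, was measured by RNA-seq in 3 lines: a control line that carries a random sgRNA, and 2 clonal knockout lines of PCIF1, called KO1 and KO2. PCIF1 is the enzyme that methylates the adenosine next to the mRNA cap to give m6Am. Each line had 3 biological replicates, A to C, which gave 9 libraries of input mRNA. The series lists 9 further libraries of m6A-immunoprecipitated mRNA, which were not analysed here. The deposited values were log2 TPM, length-normalised transcript abundances, of 15258 genes, and 14512 genes with a mean of at least 1 TPM were tested. Reads counted on genes, recovered from the values, ranged from 7848089 to 11393206 per library and summed to 84602764. In a principal component analysis the first component held 51% of the variance and separated the 3 control libraries (-48.7 to -46.0) from the 6 knockout libraries (22.1 to 24.6). The second component held 25.1% and separated KO1 (28.1 to 29.9) from KO2 (-28.6 to -27.8). Replicates of a line correlated across genes with r from 0.986 to 0.989.

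PCIF1 itself (ENSG00000100982, chromosome 20, 45934683 to 45948023 in hg38) was lower in KO1 and not in KO2. Its level was 57.6 ± 3.84 TPM in control, 24.0 ± 1.76 TPM in KO1 and 60.3 ± 3.86 TPM in KO2 (SD, n = 3 each). KO1 thus held 41.6% of the control level, with a log2 fold change of -1.26 (SE 0.0735, limma adjusted p = 1.65e-06). In KO2 the log2 fold change was 0.07 (95% confidence interval -0.098 to 0.23, limma adjusted p = 0.542). The 3 KO1 libraries held 199, 205 and 210 PCIF1 reads, against 466 to 577 in the control and 459 to 532 in the KO2 libraries. The exact two-sided permutation test of 3 against 3 gave p = 0.1 for KO1 against control, the smallest it can give, and p = 0.5 for KO2 against control. KO2 exceeded KO1 by 1.33 on the log2 scale (limma adjusted p = 2.54e-06, exact permutation p = 0.1). A frameshift edit need not lower the mRNA, so the level in KO2 checks neither its genotype nor its label. The position and sequence of the edits are not given in the sources used here.

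**Figure D1:**
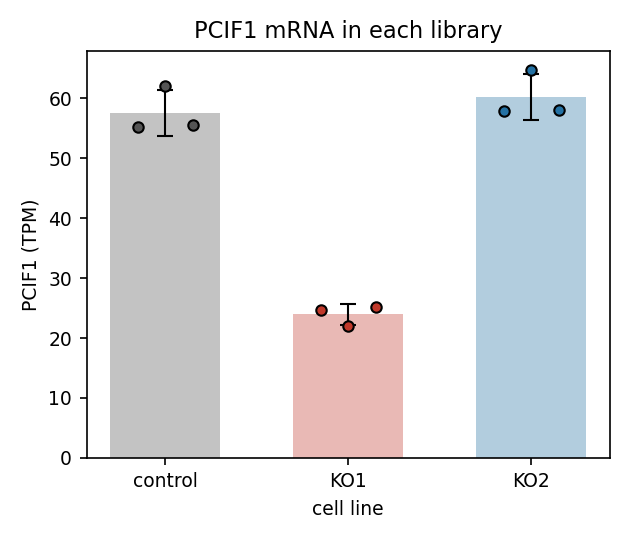
PCIF1 mRNA in TPM (vertical axis, from 0) for the 3 cell lines; bars are means, error bars are SDs and points are the 3 libraries of each line. The KO1 libraries lie between 22.0 and 25.3 TPM, and the control and KO2 libraries between 55.2 and 64.7 TPM.

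The comparison of each clone with the control line asks which mRNAs differ in cells edited at PCIF1. In KO1, ELMO1, a regulator of Rac signalling and cell migration, was 185-fold lower by its reads (95% counting interval 32.9 to 7360; 185 reads in control, 1 in KO1). EMC10, a subunit of the endoplasmic reticulum membrane protein complex, fell from 10.6 ± 0.402 to 0.104 ± 0.0468 TPM (SD, n = 3; limma adjusted p = 1.19e-07). The hypoxia-induced carbonic anhydrase CA9 fell from 45.2 ± 4.75 to 0.443 ± 0.153 TPM (limma adjusted p = 7.22e-08). GSPT2, a translation termination factor, was 141-fold lower by its reads (95% counting interval 24.9 to 5620). FAM133A rose from 0.243 ± 0.192 to 4.94 ± 1.03 TPM (limma adjusted p = 0.00208), and the caveolae protein gene CAVIN2 from 0.456 ± 0.123 to 10.8 ± 0.742 TPM (limma adjusted p = 1.13e-07). The adhesion receptor gene ADGRF1 rose by 4.87 on the log2 scale (SE 0.385, limma adjusted p = 1.36e-05). MACROH2A2, which encodes a histone variant, had no read in control and was at least 7.65-fold higher in KO1. Across the transcriptome 4975 of 14512 genes (34.3%) passed a limma adjusted p of 0.05, of which 2928 were higher and 2047 lower in KO1. The share of higher genes was 58.9% as deposited and 48.7% after each library was centred on its median, so it depends on the scaling. The floor behind each "at least" value is 3 reads over the 3 libraries of a line, and bounds and intervals cover counting error only.

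Of the 26 gene lists with at least 5 tested members, 11 passed camera in KO1, 5 upward and 6 downward. With a correlation estimated from the data, camera called 0 lists (2 at an unadjusted p under 0.05, lowest adjusted p = 0.282), and fry, which tests whether a list moves on balance one way without comparing it with other genes, called 19. Replication-dependent histone genes, whose mature mRNAs mostly lack a poly(A) tail, were lower: 19 of 41 fell and 2 rose (21 and 2 adjusted over the list alone; camera adjusted p = 3.79e-05; adjusted p = 0.282 with an estimated correlation). H2AC8 fell by 0.66 and H4C2 by 0.61 on the log2 scale (limma adjusted p = 0.000317 and 0.000197), while H2BC14 rose by 0.58. Histone genes have close copies and lie side by side on chromosome 6, so single values are uncertain. Among cytosolic ribosomal protein genes, 35 of 79 fell and 3 rose (37 and 3 adjusted over the list alone; camera adjusted p = 1.29e-05; adjusted p = 0.449 with an estimated correlation), with a median log2 fold change of -0.0991. RPL22 was among the 3 that rose, by 0.27 on the log2 scale (limma adjusted p = 0.00146). Of 76 mitochondrial ribosomal protein genes, 13 fell and 3 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.025; adjusted p = 0.449 with an estimated correlation). Of 60 nuclear genes of oxidative phosphorylation, 15 fell and 4 rose (15 and 4 adjusted over the list alone; camera adjusted p = 0.025; adjusted p = 0.449 with an estimated correlation).

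Glycolysis and hypoxia genes were also lower in KO1: 12 of 32 fell and 5 rose (15 and 6 adjusted over the list alone; camera adjusted p = 0.025; adjusted p = 0.449 with an estimated correlation). Besides CA9, NDRG1 fell by 0.81 and ENO2, a glycolytic enolase, by 0.43 on the log2 scale (limma adjusted p = 4.25e-06 and 0.000263). Extracellular matrix genes fell in 14 of 28 cases and rose in 8 (15 and 9 adjusted over the list alone; camera adjusted p = 0.0406; adjusted p = 0.628 with an estimated correlation). COL6A2 fell by 3.93 and VCAN by 0.95 on the log2 scale, whereas the proteoglycan gene BGN rose from 14.7 ± 0.498 to 93.8 ± 3.98 TPM (limma adjusted p = 1.73e-08).

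Mitochondrially encoded genes rose in KO1 in 10 of 13 cases and fell in none (10 and 0 adjusted over the list alone; camera adjusted p = 0.00204; adjusted p = 0.47 with an estimated correlation). MT-CYB rose by 0.86 and MT-ND2 by 0.58 on the log2 scale (limma adjusted p = 5.71e-06 and 0.000154). The share of reads on all mitochondrial genes, ribosomal RNAs included, was 3.37 to 3.70% in the KO1 and 3.48 to 3.73% in the control libraries. Targets of p53 rose in 10 of 29 cases and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.025; adjusted p = 0.282 with an estimated correlation). MDM2, the ubiquitin ligase that acts on p53, rose by 0.88 and SESN2 by 0.49 on the log2 scale (limma adjusted p = 7.84e-06 and 0.000212). Of the 14 m6A reader genes, 7 rose and none fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.0292; adjusted p = 0.449 with an estimated correlation). YTHDF3 rose by 0.34 and YTHDF1 by 0.30 on the log2 scale (limma adjusted p = 0.00104 and 0.00158). Decapping and decay genes rose in 12 of 38 cases and fell in 3 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0292; adjusted p = 0.449 with an estimated correlation). SMG6, the endonuclease of nonsense-mediated decay, rose by 0.55 and SMG5 by 0.40 on the log2 scale. Interferon-stimulated genes rose in 12 of 32 cases and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.0292; adjusted p = 0.449 with an estimated correlation). IRF1 rose by 0.86 and IFIT3 by 0.78 on the log2 scale (limma adjusted p = 0.00022 and 3.09e-05).

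The KO1 calls of the decay, interferon and m6A reader lists ended without control replicate C (camera adjusted p = 0.0655, 0.0655 and 0.0627), as did that of the extracellular matrix list (0.0783), which also ended without control replicate B (0.0623) or KO1 replicate B (0.0629). With a trend on GC content and length subtracted, an alternative chosen after seeing the data, the calls of the reader (0.1), interferon (0.0791), decay (0.051), mitochondrial ribosomal (0.077) and oxidative phosphorylation (0.077) lists ended.

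In KO2, TP73-AS1, annotated as a transcribed unitary pseudogene, was at least 115-fold higher than in control, where it had no read. SERPINB5, an epithelial serpin, was at least 38.1-fold higher and MACROH2A2, in a stretch of chromosome 10 that was higher in KO2, at least 66.1-fold. CAVIN2 rose to 60.2 ± 0.991 TPM (SD, n = 3), 7.08 above control on the log2 scale (SE 0.182, limma adjusted p = 6.04e-09). QPCT, a glutaminyl cyclase, had no read in KO2 and was at least 8.05-fold lower, against 26 reads in control. PLAGL1, an imprinted zinc finger gene, fell from 4.78 ± 0.409 to 0.315 ± 0.0914 TPM (limma adjusted p = 1.2e-06). FABP6, a bile acid binding protein gene, was 23.2-fold lower by its reads (95% counting interval 6.1 to 197), and FOXN3-AS1 14.5-fold lower (4.68 to 73.1). The strand setting of the counting is not given in the sources used here, so values of TP73-AS1 and FOXN3-AS1, which their symbols mark as antisense, are uncertain. Over all tested genes 4414 (30.4%) passed a limma adjusted p of 0.05 in KO2, 2266 higher and 2148 lower.

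Of the same 26 lists, 8 passed camera in KO2, 4 upward and 4 downward. Of the 10 splits of the control and KO2 libraries into 3 and 3, 3 gave at least 8 lists, the real split included, and the highest gave 12. With an estimated correlation camera called 0 (3 at an unadjusted p under 0.05), and fry called 18. Among cytosolic ribosomal protein genes, of which more fell than rose in KO1, 23 of 79 rose here and none fell (23 and 0 adjusted over the list alone; camera adjusted p = 3.48e-05; adjusted p = 0.405 with an estimated correlation). RPL22 rose by 0.32 and RPL11 by 0.15 on the log2 scale (limma adjusted p = 0.000473 and 0.00551). Genes of cap-dependent translation initiation rose in 13 of 35 cases and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 0.000998; adjusted p = 0.339 with an estimated correlation). The poly(A)-binding protein gene PABPC1 rose by 0.31 and the scaffold gene EIF4G3 by 0.33 on the log2 scale, as did EIF4E2 by 0.53, which lies in a stretch of chromosome 2 that was higher in both clones. Cholesterol synthesis genes rose in 9 of 24 cases and fell in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.02; adjusted p = 0.405 with an estimated correlation), a call that ended without control replicate A (0.0692). CYP51A1 rose by 1.18 on the log2 scale (limma adjusted p = 1.2e-06). Genes of the integrated stress and unfolded protein responses rose in 17 of 33 cases and fell in 6 (17 and 6 adjusted over the list alone; camera adjusted p = 0.02; adjusted p = 0.405 with an estimated correlation). CHAC1 rose by 0.76 and the cystine transporter gene SLC7A11 by 0.52 on the log2 scale, while TRIB3, in a stretch of chromosome 20 that was lower in both clones, fell by 0.28.

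Extracellular matrix genes were lower in KO2: 19 of 28 fell and 3 rose (21 and 3 adjusted over the list alone; camera adjusted p = 2.39e-06; adjusted p = 0.405 with an estimated correlation). MMP3 fell by 1.77 and VCAN by 1.31 on the log2 scale, and BGN rose by 2.18 (limma adjusted p = 1.11e-05, 2.26e-05 and 6.41e-08). Genes of the dedifferentiated, invasive melanoma state fell in 20 of 31 cases and rose in 3 (20 and 3 adjusted over the list alone; camera adjusted p = 2.82e-05; adjusted p = 0.405 with an estimated correlation). TGFBI fell from 46.1 ± 1.84 to 11.4 ± 1.58 TPM and NGFR by 1.81 on the log2 scale, whereas THBS1 rose by 0.59 (limma adjusted p = 3.6e-07, 0.00317 and 2.59e-05). Antigen presentation genes fell in 8 of 23 cases and rose in none (8 and 0 adjusted over the list alone; camera adjusted p = 0.000344; adjusted p = 0.339 with an estimated correlation). CD74, the class II invariant chain, fell from 88.0 ± 3.40 to 18.4 ± 1.03 TPM and PSMB8 by 0.37 on the log2 scale (limma adjusted p = 4.5e-09 and 0.000153). Histone genes fell in 14 of 41 cases and rose in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.000993; adjusted p = 0.339 with an estimated correlation), and H2AC8 fell by 0.33 on the log2 scale (limma adjusted p = 0.0146).

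Other lists passed camera in neither clone. Melanocyte lineage and pigmentation genes had 12 of 32 members at a tested level, of which 4 rose and 4 fell in KO1 and 4 rose and 4 fell in KO2, the same numbers as adjusted over the list alone (camera adjusted p = 0.578 and 0.558). ERBB3 fell in both clones, with log2 fold changes of -2.16 in KO1 and -1.91 in KO2, and RAB38 rose by 0.68 and 0.83. Cap and m6A writer and eraser genes, a list that includes PCIF1, rose in 5 of 23 cases and fell in 6 in KO1 (7 and 7 adjusted over the list alone; camera adjusted p = 0.629), and rose in 2 and fell in 3 in KO2 (2 and 3 adjusted over the list alone; camera adjusted p = 0.764). RNMT, the cap guanine methyltransferase, had log2 fold changes of -0.59 in KO1 and -0.30 in KO2 and METTL4 of -0.63 and -0.54, and both lie in a stretch of chromosome 18 that was lower in both clones. TGF-beta and BMP response genes rose in 5 of 18 cases and fell in 6 in KO1 (5 and 6 adjusted over the list alone; camera adjusted p = 0.518), and rose in 2 and fell in 4 in KO2 (2 and 4 adjusted over the list alone; camera adjusted p = 0.412). The activin antagonist gene FST rose from 217 ± 1.86 TPM to 412 ± 14.6 in KO1 and 412 ± 2.30 in KO2 (limma adjusted p = 6.12e-08 and 6.41e-08).

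NF-kappaB and inflammatory genes rose in 4 of 16 cases and fell in 1 in KO1 (2 and 1 adjusted over the list alone; camera adjusted p = 0.483), and rose in 1 and fell in 3 in KO2 (1 and 3 adjusted over the list alone; camera adjusted p = 0.24). IL1B fell by 2.18 on the log2 scale in KO2, and TNFAIP2 rose by 0.41 and 0.62 in KO1 and KO2. Cancer testis antigen genes rose in 5 of 15 cases in KO1 and in 3 in KO2 and fell in none, as also adjusted over the list alone (camera adjusted p = 0.174 and 0.115), and PRAME rose by 0.85 and 0.79. Immediate early genes rose in 2 of 17 cases and fell in 3 in KO1, and rose in 4 and fell in 2 in KO2, as also adjusted over the list alone (camera adjusted p = 0.806 and 0.722). KLF6 rose by 0.36 and 0.46 on the log2 scale, and DUSP1 had log2 fold changes of -0.47 and -0.25. The median, the mean and the camera direction differed in sign for the immediate early list in both clones, the writer and eraser list in both clones and the PCIF1 neighbour list in KO2. Markers of other cell types had too few tested members for a list test. Both tested endothelial markers rose in both clones, ESAM by 1.13 and 1.37 and EGFL7 by 0.81 and 0.78 on the log2 scale. The fibroblast marker LUM had 1 read in control and was 56.9-fold higher in KO1 (95% counting interval 9.81 to 2290) and 28.0-fold higher in KO2 (4.6 to 1150). Of 4 epithelial markers, 3 fell in KO1, and in KO2 1 rose and 1 fell, and KRT18 had log2 fold changes of -0.16 and -0.30. The tested lymphoid and myeloid marker CSF1R passed in neither clone, at 1.19 ± 0.0756 TPM in control, 1.24 ± 0.435 in KO1 and 0.995 ± 0.248 in KO2.

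The design holds 2 clones, so that genes changed in both can be told from genes changed in 1. PNMA8A (ENSG00000182013), MGMT (ENSG00000170430), GLB1L2, MEOX2, PDE3B and the non-coding gene MIR3667HG had no read in the 3 control libraries and rose in both clones. MGMT, the DNA repair enzyme that removes alkyl groups from guanine (chromosome 10, 129467190 to 129770983), reached 15.8 ± 0.400 TPM in KO1 and 19.2 ± 0.374 TPM in KO2 (SD, n = 3), at least 149-fold and 186-fold above control. For PNMA8A the bounds were 175-fold and 213-fold, for GLB1L2 116-fold and 75.8-fold, for MEOX2 62.6-fold and 75.8-fold, for PDE3B 42.3-fold and 63.6-fold and for MIR3667HG 37.9-fold and 61.4-fold. RELN (ENSG00000189056), which encodes the secreted glycoprotein reelin, had 3 reads in control and was 587-fold higher in KO1 (95% counting interval 201 to 2850) and 464-fold higher in KO2 (159 to 2250). The phospholipid transporter gene ATP10A was 189-fold higher in KO1 (33.5 to 7490) and 87.3-fold in KO2 (15.2 to 3490). In KO2 MGMT lies in a stretch of chromosome 10 with a median log2 fold change of 0.356.

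Conversely, COBL (ENSG00000106078), an actin nucleator, FAM111B (ENSG00000189057), a serine protease gene, and SPATA21 had no read in either clone. COBL was at least 226-fold lower in KO1 and 209-fold in KO2, FAM111B 117-fold and 108-fold, and SPATA21 58.4-fold and 54.2-fold. The neural adhesion molecule gene NCAM1 was 391-fold lower in KO1 (95% counting interval 69.7 to 15500) and at least 121-fold lower in KO2. TRBC2, a T cell receptor constant region gene, fell from 155 ± 6.98 TPM to 0.302 ± 0.294 in KO1 and 0.476 ± 0.603 in KO2, and its neighbour TRBC1 was at least 52.1-fold and 48.3-fold lower. POTEC had log2 fold changes of -7.87 in KO1 and -7.01 in KO2. CXADRP3 fell by 6.48 on the log2 scale in KO1 and was 200-fold lower by its reads in KO2 (95% counting interval 55 to 1660). TRBC1 and TRBC2, POTEC and CXADRP3 have near-identical copies, so their single values are uncertain, and the latter pair lies in the lower stretch of chromosome 18.

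In all, 2283 genes (15.7%) passed in both clones with the same direction, 1229 higher and 1054 lower, and 304 of these (2.09%) changed at least 2-fold in both, 164 upward and 140 downward. Another 195 genes passed in both with opposite directions. Independent lists of these sizes would share 457.2 higher and 303 lower genes. With KO1 or KO2 in place of control as the reference, 1944 and 1742 genes were shared in the same direction. Unchanged groups simulated against the same control libraries gave 0.02 shared genes on average over 50 simulations. Across genes, which are not independent replicates, the log2 fold changes of the clones correlated with r = 0.72, against 0.50 in these simulations. The covariance was 0.285 against 0.0142 simulated, a difference of 0.27. The same sign was seen for 69.8% of genes, against 66.7% simulated. With 3 control libraries no split leaves at least 2 to each clone, so part of the excess in shared genes and same signs may come from the shared controls. The simulated r of 0.50 comes from noise alone. The observed covariance lay far above the simulated maximum of 0.0157, which argues against noise of the shared controls as the main source of r = 0.72. Noise of the shared control libraries adds the same covariance with or without real effects, so the difference in covariance leaves that noise out. A difference of the control line itself from both clones remains in that value.

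**Figure D2:**
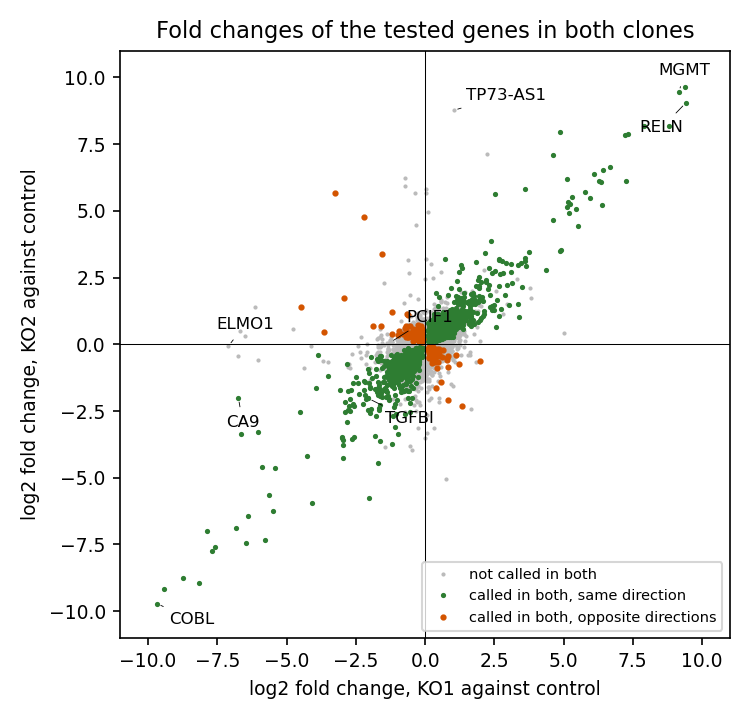
Log2 fold change against control of each of the 14512 tested genes in KO1 (horizontal axis) and KO2 (vertical axis); green points are the 2283 genes called in both clones with the same direction, orange points the 195 called with opposite directions and grey points the other genes. MGMT and RELN lie at the upper right, COBL at the lower left, and ELMO1 and TP73-AS1 far from 0 in 1 clone.

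Neighbouring genes shifted together along the genome. Windows of 25 consecutive tested genes were formed after the data had been seen, and a stretch was defined as at least 2 consecutive windows with medians beyond 0.25 in the same direction. In both clones 75 genes of chromosome 18 (158383 to 21526112), from USP14 to GREB1L and including TYMS, RNMT, METTL4 and NDUFV2, were lower as a group, with medians of -0.474 in KO1 and -0.508 in KO2, and 52 fell in both. The same held for 75 genes of chromosome 20 (270863 to 13638932), including PCNA, TRIB3 and MRPS26, with medians of -0.526 and -0.523 and 55 genes that fell in both. PCIF1 lies on the other arm of chromosome 20, outside this stretch. On chromosome 2, 75 genes from ITGAV to NBEAL1 (186590010 to 203226378), including CAVIN2 and NDUFB3, had medians of 0.505 and 0.412, and 75 genes from CAB39 to DTYMK (230712842 to 241686944) had medians of 0.486 and 0.453. KO2 also had higher medians over 150 and 225 genes of chromosome 10 (42513510 to 79677996, median 0.555, and 87094161 to 131981967, median 0.356), where KO1 had 0.063 and -0.00115. Over 75 and 300 genes of chromosome 3 (3126933 to 15601852 and 27214816 to 88168729) KO2 had medians of 0.597 and 0.381 and KO1 0.0606 and 0.051. In KO1, 50 genes of chromosome 5 (140794852 to 141636849), mostly protocadherins, had a median of 0.593, against 0.058 in KO2, but alpha and gamma protocadherin genes overlap and share exons, so their counts are not independent. Chromosome 19 held a pair of stretches in KO1 (19145569 to 29824312 and 55641062 to 58431736), with medians of 0.475 and 0.297, against 0.198 and 0.229 in KO2. In 50 histone-cluster genes of chromosome 6 (26043227 to 27893106) the median was -0.267 in KO2, where they formed a stretch, and -0.26 in KO1. Stretches held 361 of the genes called in KO1 (7.26%) and 791 of those called in KO2 (17.9%), and 1000 random gene orders gave no stretch. Of the 14512 tested genes, called or not, 500 lay in the stretches of KO1 and 1100 in those of KO2. Stretches were chosen by fold change, so a higher share among called genes is built in.

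**Figure D3:**
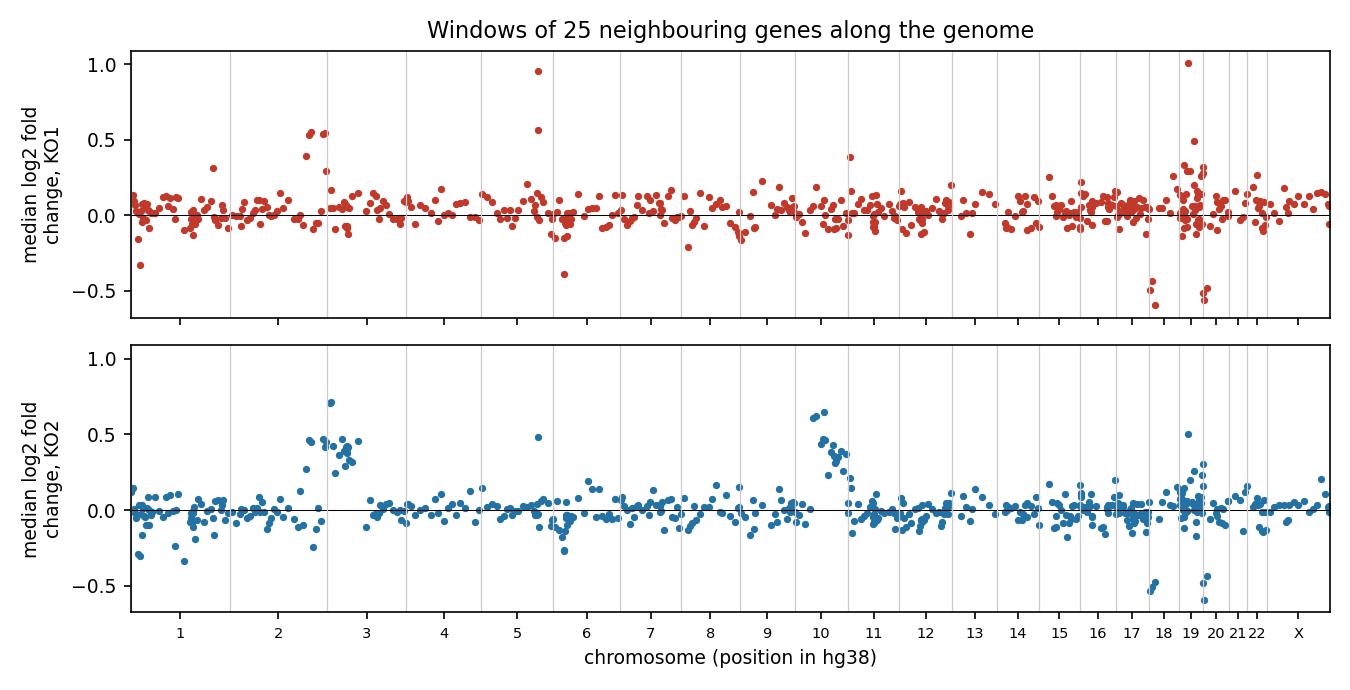
Median log2 fold change against control of windows of 25 neighbouring tested genes (vertical axis) by position in hg38 (horizontal axis, chromosomes 1 to 22 and X) for KO1 and KO2; each point is a window. Windows at the start of chromosomes 18 and 20 lie below 0 in both clones, and those of chromosomes 3 and 10 lie above 0 in KO2.

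The direct comparison of KO2 with KO1 tests the difference between clones that carry the same genotype label. Cytosolic ribosomal protein genes were higher in KO2 than in KO1: 57 of 79 passed upward and none downward (63 and 0 adjusted over the list alone; camera adjusted p = 4.93e-19; adjusted p = 0.125 with an estimated correlation), with a mean difference of 0.203 on the log2 scale. Their mean deviation from the control mean was between -0.0987 and -0.0692 in the 3 KO1 libraries and between 0.0901 and 0.16 in the 3 KO2 libraries. Of the p53 targets, 15 of 29 were lower in KO2 than in KO1 and 3 higher (17 and 3 adjusted over the list alone; camera adjusted p = 0.00225; adjusted p = 0.115 with an estimated correlation). The cell cycle inhibitor gene CDKN1A held 140 ± 1.84 TPM in control, 166 ± 8.21 in KO1 and 86.4 ± 1.04 in KO2, a difference of -0.94 between the clones (limma adjusted p = 5.72e-07). MDM2 differed by -0.80 and BTG2 by -1.02. Cell cycle genes were lower in KO2 in 26 of 44 cases and higher in 4 (27 and 5 adjusted over the list alone; camera adjusted p = 0.00144; adjusted p = 0.115 with an estimated correlation), with TYMS differing by -0.15. Lysosomal genes were lower in 17 of 32 cases and higher in 3 (21 and 3 adjusted over the list alone; camera adjusted p = 0.00225; adjusted p = 0.125 with an estimated correlation), with CTSB differing by -0.22. Of the 13 mitochondrially encoded genes 10 were lower and none higher (10 and 0 adjusted over the list alone; camera adjusted p = 0.000958; adjusted p = 0.416 with an estimated correlation), with MT-CYB differing by -0.56.

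Of the m6A readers, 8 of 14 were lower in KO2 than in KO1 and none higher (10 and 0 adjusted over the list alone; camera adjusted p = 0.0139; adjusted p = 0.353 with an estimated correlation), and YTHDF1 differed by -0.27. Genes of the invasive melanoma state were lower in 14 of 31 cases and higher in 2 (14 and 2 adjusted over the list alone; camera adjusted p = 0.00415; adjusted p = 0.416 with an estimated correlation), and THBS1 differed by -0.77. Extracellular matrix genes were lower in 17 of 28 and higher in 4 (18 and 6 adjusted over the list alone; camera adjusted p = 0.0156; adjusted p = 0.49 with an estimated correlation), and MMP3 differed by -1.20. Antigen presentation genes were lower in 10 of 23 and higher in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0103; adjusted p = 0.368 with an estimated correlation), and CD74 differed by -0.62. Genes downstream of MAPK signalling were lower in 7 of 19 and higher in 1, as also adjusted over the list alone (camera adjusted p = 0.0375; adjusted p = 0.49 with an estimated correlation). In KO1 5 of the 19 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.806), and in KO2 2 rose and 9 fell (2 and 10 adjusted over the list alone; camera adjusted p = 0.109), with SPRED2 higher by 0.32 and 0.31. The 10 tested neighbours of PCIF1 held 5 lower genes and none higher, as also adjusted over the list alone (camera adjusted p = 0.0448; adjusted p = 0.353 with an estimated correlation), and PLTP differed by -0.46. Against control 4 of these neighbours rose and 1 fell in KO1, and 1 rose and 3 fell in KO2 (camera adjusted p = 0.578 and 0.558).

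Upward in KO2 against KO1 were the mitochondrial ribosomal protein genes, 17 of 76 higher and 2 lower (15 and 1 adjusted over the list alone; camera adjusted p = 0.00109; adjusted p = 0.344 with an estimated correlation), and the nuclear oxidative phosphorylation genes, 16 of 60 higher and 3 lower, as also adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.379 with an estimated correlation). MRPS25, in a stretch of chromosome 3 that was higher in KO2, differed by 0.43. Altogether 4165 genes (28.7%) passed limma between the clones, 1711 higher and 2454 lower in KO2, and 13 lists passed camera, 3 upward and 10 downward. With an estimated correlation camera called 0 (4 at an unadjusted p under 0.05), and fry called 20. The call of the oxidative phosphorylation list ended without KO2 replicate C (camera adjusted p = 0.0797), that of the extracellular matrix list likewise (0.0568), and those of the MAPK and PCIF1 neighbour lists without KO1 replicate A (0.0774 and 0.0797) or KO2 replicate C (0.111 and 0.111).

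**Figure D4:**
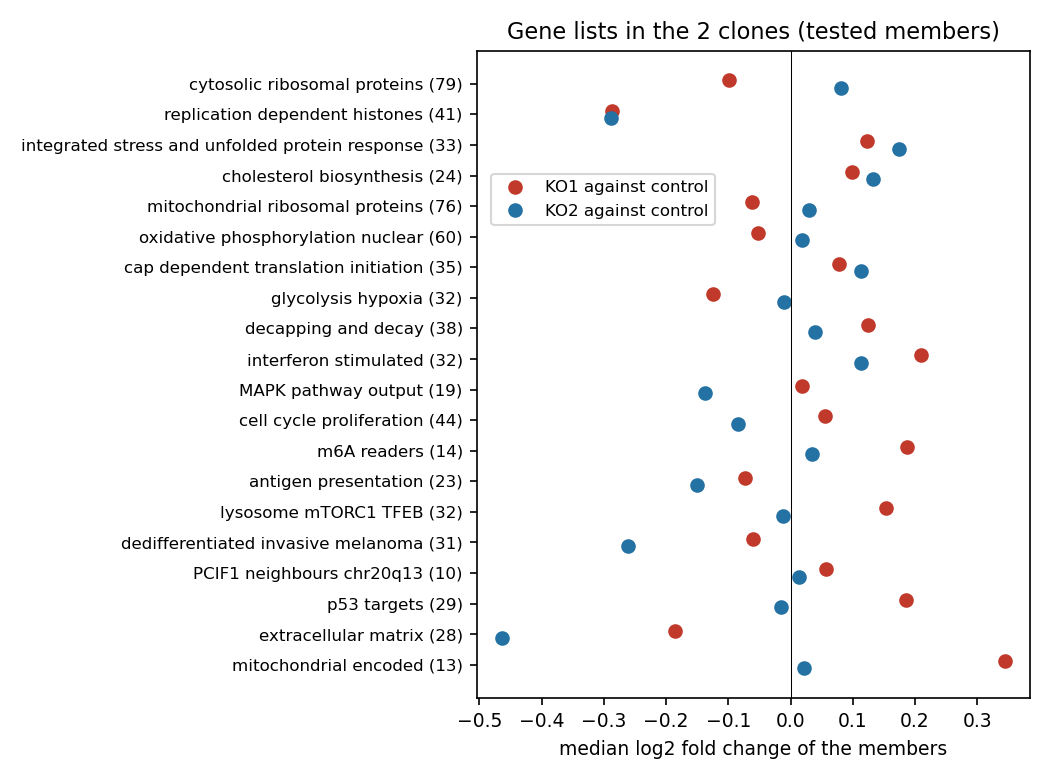
Median log2 fold change against control (horizontal axis) of the tested members of each gene list that passed camera in at least 1 comparison, in KO1 (red) and KO2 (blue), with the number of tested members in parentheses. The median of the 79 cytosolic ribosomal protein genes is -0.0991 in KO1 and 0.0818 in KO2, and that of the 28 extracellular matrix genes is below 0 in both clones.

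Averaged over both clones, 4987 genes (34.4%) passed limma against control, 2807 higher and 2180 lower. These p-values measure the spread between libraries of a line, since the design has 1 control line and 2 clones. The SD of the log2 fold changes was 0.63 in both KO1 and KO2 and 0.47 between the clones. Changes were below 0.5 on the log2 scale for 83.6% of genes in KO1 and 84.1% in KO2. Genes that fell in both clones within the tested lists included NDRG1, with log2 fold changes of -0.81 and -0.83, and TGFBI, with -2.06 and -2.02. Genes that rose in both included PRAME, CYP51A1, FST and the replication helicase gene MCM4, the last by 0.49 and 0.47.

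PCIF1 acts on mRNAs that start with adenosine, so tested genes were grouped by the base at their annotated start. The 5761 genes with A at the most upstream annotated start had a median log2 fold change of 0.0355 in KO1, against 0.0339 for the other genes, and of 0.0064 against 0.0116 in KO2. Camera gave adjusted p = 0.979 for A-start genes in KO1 and 0.935 in KO2 (0.967 and 0.906 with an estimated correlation). With the start of the canonical transcript the values were 0.886 and 0.82 (0.858 and 0.777). At the preset correlation camera has little power for sets this large, so these values do not exclude a small shift. Of all start bases, only C at the canonical start passed, in KO2 against KO1 and only with an estimated correlation (camera adjusted p = 0.0142). At the preset correlation its adjusted p was 0.194. Annotated starts only approximate the starts that these cells use.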

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

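Among the tests of this part, those of swapped libraries and of members without a listed pseudogene were chosen only after the result had been seen, and so was the trend on GC content and length. Every result here was singled out because the clones, which carry the same genotype label, differed by a test of the difference itself.

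PCIF1 was 1.33 higher on the log2 scale in KO2 than in KO1: its mRNA was lower than control in KO1 and did not pass the test in KO2 (log2 fold change 0.07, 95% confidence interval -0.098 to 0.23). A loss of copies of the region does not account for it: the 10 tested neighbours had a median log2 fold change of 0.0562 in KO1 (95% bootstrap interval -0.0879 to 0.259), above the bound of -0.632 set for it, which is 0.5 of the PCIF1 change. A swap of a single KO1 with a single KO2 library does not account for it either: over the tested genes without PCIF1, 0 libraries of either clone correlated best with a library of the other clone. An exchange of the labels of whole lines was not tested. Different edits in the clones stay open as a biological explanation, which was not tested, since the edited sequences were not used here.

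Of 79 cytosolic ribosomal protein genes, 35 fell and 3 rose in KO1 (camera adjusted p = 1.29e-05; adjusted p = 0.449 with an estimated correlation), 23 rose and none fell in KO2 (3.48e-05; 0.405), and the list differed between clones (camera adjusted p = 4.93e-19; adjusted p = 0.125 with an estimated correlation). The mean difference of 0.203 on the log2 scale was 0.185 after the GC and length trend had been subtracted, and at least 88.6% of it was kept with any library left out, which argues against that trend as the whole source. Reads shared with listed pseudogene copies are not the whole source, since the 39 members without a listed pseudogene still differed by 0.184 (95% bootstrap interval 0.153 to 0.216). A part played by such reads stays open: the 40 members with one differed by 0.0387 more (95% bootstrap interval -0.0204 to 0.101), which does not decide. The mean of the list lay below the control mean in 3 of 3 KO1 libraries and above it in 3 of 3 KO2 libraries. A biological difference between the clones stays open and was not tested.

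Between KO2 and KO1 4165 genes passed limma, and 195 genes passed against control in opposite directions and also passed this test. Further named genes past the test of the difference, beyond those given singly, numbered 49. KO2 minus KO1 on the log2 scale was 7.03 for ELMO1, 6.30 for EMC10, 4.73 for CA9 and 7.20 for GSPT2, which were low in KO1. It was -4.58 for FAM133A, 3.08 for MACROH2A2 and 2.48 for CAVIN2. It was 7.74 for TP73-AS1 and 4.89 for SERPINB5, and -5.78 for QPCT, -2.78 for FABP6 and -3.47 for PLAGL1. For ADGRF1 it was -1.36 (limma adjusted p = 0.0251), a call that ended without KO1 replicate A (0.0731), B (0.0779) or C (0.0521) or KO2 replicate A (0.0853) or B (0.0542). For FOXN3-AS1 it was -2.43 (limma adjusted p = 0.0364), a call that ended without KO1 replicate A (0.068), B (0.0769) or C (0.102) or KO2 replicate C (-1.48, 0.0736). It also ended with the replicate block (0.0603), quantile normalization (0.0528), no variance trend (0.0658), log2(TPM + 1) (-0.97, 0.0664) and log2(TPM + 5) (-0.32, 0.219). Fitted values of genes with few reads in a line depend on the prior count and are not bounds.

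Other lists that camera found to differ between the clones were antigen presentation (adjusted p = 0.0103), cell cycle (0.00144), the dedifferentiated state (0.00415), extracellular matrix (0.0156), lysosome (0.00225), m6A readers (0.0139), MAPK output (0.0375), mitochondrially encoded genes (0.000958), mitochondrial ribosomal proteins (0.00109), oxidative phosphorylation (0.0103), p53 targets (0.00225) and the neighbours of PCIF1 (0.0448), and 0 of them passed with an estimated correlation.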

How the results depend on the processing

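The running median of neighbours, the GC and length trend and voom were chosen after seeing the data. Main counts of called genes stayed within 1.5 times under every alternative run except those of genes changed at least 2-fold in both clones: 304 became 178 (85 higher, 93 lower) with log2(TPM + 1), 64 (28 and 36) with log2(TPM + 5) and 122 (64 and 58) with a mean of at least 5 TPM. The larger offsets shrink fold changes of low genes and the filter removes them, by construction. For the same reason the SD of log2 fold changes, 0.63 in each clone, became 0.41 in KO1 and 0.41 in KO2 with log2(TPM + 1), and 0.28 and 0.27 with log2(TPM + 5). Voom called 5604 genes in KO1, 5059 in KO2, 4660 between the clones, 2686 in both clones and 323 at least 2-fold in both. The direction of the many small changes depends on the scaling. In KO1 58.9% of calls were higher as deposited, 48.7% with median centring (2410 and 2538) and 47.1% with voom (2639 and 2965). For KO2 against KO1 41.1% became 51.7% with median centring (2043 and 1911). For the mean of both clones 56.3% became 45.9% with voom, and for genes called in both clones 53.8% became 43.3% (1162 and 1524). Medians over all genes moved by less than 0.1, and no list that camera called turned the sign of its median under these scalings. Numbers of called members moved too: in KO1 13 lower mitochondrial ribosomal genes became 20 with median centring and 25 with voom, and 35 lower cytosolic ribosomal genes 46 and 52, and between the clones 8 lower m6A readers became 4 with median centring.

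Lists called by camera fell from 11 to 0 in KO1, from 8 to 0 in KO2 and from 13 to 0 between the clones with an estimated correlation. The estimated correlations of the p53 targets (-0.0197) and of the cell cycle genes (0.00792) lay below the preset 0.01. A higher correlation between members thus does not account for the lost calls of these lists. With an estimated correlation camera also relies on the 6 residual degrees of freedom, which lowers its power. In KO1 6 were called with the GC and length trend subtracted (2 up, 4 down) and 5 with the running median of neighbours subtracted (1 up, 4 down). The latter removes the shift of clustered lists by construction, so the calls of histones (0.167 in KO1, 0.52 in KO2) and mitochondrially encoded genes (0.549 in KO1, 0.216 between the clones) ended. Under it the KO1 calls of decay (0.0623), extracellular matrix (0.168), interferon (0.0665) and m6A reader genes (0.0521) and the call of the PCIF1 neighbours between the clones (0.133) ended as well, and with the GC and length trend subtracted that of oxidative phosphorylation between the clones (0.0561). For these lists the cause was not tested. Leaving out 1 library gave 7 to 11 lists in KO1, with 7 without control replicate C, 7 to 9 in KO2 and 9 to 14 between the clones. The KO1 call of the extracellular matrix list also ended with the replicate letter as a block (0.056), quantile normalization (0.0636), median centring (0.0765) and a mean of at least 5 TPM (0.125), and that of decay with median centring (0.0514). In KO2 the cell cycle list (0.0559) passed with quantile normalization (0.0261), a mean of at least 5 TPM (0.0481), the running median subtracted (0.0425) and without KO2 replicate A (0.0377), and the MAPK list (0.109) with a mean of at least 5 TPM (0.0372) and without KO2 replicate B (0.0305). Between the clones the lists of initiation (0.041, GC and length trend), cholesterol synthesis (0.0306, running median), NF-kappaB (0.0447, running median; 0.0468 without KO1 replicate C) and histones (0.0491 without KO1 replicate B) passed only so.

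With the running median of neighbours subtracted, the counts were 4640 in KO1, 3889 in KO2, 2105 in both clones and 290 at least 2-fold in both, and 8 log2 fold changes of named genes turned positive: RNMT 0.0895 in KO2, PCNA 0.0171 in KO1 and 0.0164 in KO2, TYMS 0.0864 in KO1 and 0.0087 in KO2, TRIB3 0.28 in KO2 (limma adjusted p = 0.00295), MRPS26 0.13 in KO2 and NDUFV2 0.0572 in KO1. All lie in the lower stretches of chromosomes 18 and 20, whose shift this setting removes. For the same reason the calls of METTL4 ended (-0.63 to -0.16 in KO1, adjusted p = 0.305, and -0.54 to -0.01 in KO2, adjusted p = 0.964, with SEs of 0.11 before and 0.113 after), as did that of EIF4E2 in KO2, in a higher stretch of chromosome 2 (0.53 to 0.12, SE 0.0446 and 0.0435, adjusted p = 0.0697), and that of H2AC8 in KO2, in the histone cluster (-0.33 to -0.12, SE 0.0855 and 0.0877, adjusted p = 0.358). RPL22 in KO1 went from 0.27 (SE 0.0444) to 0.16 (SE 0.0652, adjusted p = 0.0845), so its call ended with a smaller value and a larger SE. Leaving out 1 library gave 3758 to 5206 genes in KO1, 3401 to 4311 in KO2, 1635 to 2141 in both clones, 3548 to 4912 for the mean, 2952 to 3974 between the clones and 295 to 309 at least 2-fold. PCIF1 ranged from -1.30 to -1.20 in KO1, from 0.01 to 0.12 in KO2 and from 1.27 to 1.37 between the clones. Over the 342 values of named genes and lists beyond the main results, leaving out 1 library ended between 2 and 19 calls and started at most 2, median centring and quantile normalization each ended 5 and started 1, and voom, which was run for the genes and not for the lists, ended 2 and started 6.

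Replicate letters did not pair the libraries: same-letter correlations of deviations ranged from -0.0736 to 0.0371, and 1 of 9 libraries correlated best with its own letter. With the letter as a replicate block, 4375 genes passed in KO1, 3877 in KO2, 4380 for the mean, 3516 between the clones, 1943 in both clones and 302 at least 2-fold.

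Depth limits low genes most: with 7848089 reads in the shallowest library, a limit of 3 reads is 0.382 reads per 1e+06 reads, and bounds for genes without reads are no estimate of their fold change.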

Other observations

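Gene families, neighbouring genes, melanocyte genes and the mixture test in this part were chosen only after the values had been seen. Zinc finger genes of the ZNF family on chromosome 19 were more often higher than lower: 92 of 212 rose and 4 fell in KO1, and 48 rose and 8 fell in KO2, with median log2 fold changes of 0.337 and 0.169. The 210 ZNF genes on other chromosomes had 56 that rose and 13 that fell in KO1, with a median of 0.123, and 25 and 18 in KO2, with a median of 0.0361. Between the clones 45 of the chromosome 19 genes were lower in KO2 and 4 higher. Of 7 protocadherin beta genes, which encode neuronal adhesion proteins and have their own exons, 6 rose in KO1 and 5 in KO2, with medians of 1.65 and 0.905. All 15 alpha genes rose in KO1 and 6 in KO2, and all 22 gamma genes rose in KO1 and 0 in KO2, where their median was -0.0274, but the genes of these clusters share exons. No test set these families against other genes. Apart from the gamma genes in KO2, these medians stayed positive under median centring, quantile normalization and voom.

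MITF, the master regulator of melanocytes, held 37.1 ± 1.14 TPM in control, 26.3 ± 2.49 in KO1 and 50.02 ± 2.26 in KO2 (SD, n = 3). It thus fell by 0.50 on the log2 scale in KO1 and rose by 0.43 in KO2 (limma adjusted p = 0.000531 and 0.00127), and in KO2 it lies in the higher stretch of chromosome 3. AXL, a receptor kinase of the dedifferentiated melanoma state, was at 709 ± 11.6, 681 ± 24.2 and 662 ± 35.6 TPM in control, KO1 and KO2, and passed in neither clone. PDE3B and its neighbour CYP2R1 on chromosome 11 (14877440 to 14892231) were both near 0 in control and read in both clones, with CYP2R1 at 2.20 ± 0.285 TPM in KO1 and 2.17 ± 0.128 in KO2. ASS1, the argininosuccinate synthase gene, was at 0.287 ± 0.331 TPM in control, 13.2 ± 1.20 in KO1 and 14.2 ± 1.60 in KO2.

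The 304 genes changed at least 2-fold in both clones raise the question whether the control line, rather than the edit, differs. Copy number shifts over many neighbouring genes are not the whole source. After the running median of neighbours had been subtracted, 272 of the 304 genes were still called at least 2-fold in both clones. Only 59 of the 304 lay in a stretch, so that subtraction could hardly have removed most of them. It also leaves in place gains or losses of single genes or small groups of neighbours, which were not tested. A mixture of another line in the control libraries cannot be told apart by the test made: 8 genes, MGMT, PNMA8A, RELN and MEOX2 among them, had at least 5 TPM in each clone and at most 3 reads over the controls, between the bounds of 5 and 20 set for it. History of the cell lines other than the edit may account for any of these genes, and stays open because the design has 1 control line. Taking each line in turn as the odd one out gave 304 genes for control, 128 for KO1 and 142 for KO2. Without the 2-fold limit the counts of genes called in the same direction lay closer together, at 2283, 1944 and 1742.

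A hypothesis from the windows is that the lines differ in segments of altered copy number or expression. The SD of window medians was 0.13 in KO1 and 0.148 in KO2, above the highest of 1000 random gene orders (0.072 and 0.0655), as the hypothesis needs. Since the hypothesis came from these windows, this is no separate support for it. Segments shared by both clones on chromosomes 2, 18 and 20 may as well be a change in the control line, and those of chromosomes 3 and 10 in KO2 alone. DNA was not measured, and clustered families such as protocadherins, zinc finger genes and histones share regulation, which these tests do not separate from copy number. Stretches of either clone held 1300 of the 14512 tested genes, 422 of the 2283 genes called in both clones (18.5%) and 59 of the 304. A higher share among called genes is built in, since stretches were chosen by their fold changes.

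Regrouping the libraries tested whether random groups of libraries could give as many calls. For genes called in both clones, 1 of 100 drawn splits into 3 groups of 3, the real one, reached 2283, and the highest other drawn gave 1224. The real groups with KO1 or KO2 as the reference were not among the drawn splits and gave 1944 and 1742. For genes at least 2-fold in both, 1 of 100 drawn splits, again the real one, gave as many, with 304 against 284 in the highest other. For 6 against 3 libraries with 1 mean per side it was 1 of 84, with 2597 against 2051. Shares under 0.05 show that regrouped libraries rarely gave as many genes for these 3 counts. By deviations from gene means, every library correlated best with another of its own line (r from 0.559 to 0.735). With libraries of other lines r was at most -0.102. Splits that mix lines widen the spread within groups, so these shares largely measure that replicates of a line are alike. The shares do not exclude chance differences between lines, since the design has 1 control line and 2 clones. For KO1, KO2 and KO2 against KO1 the 10 splits of 3 against 3 are too few for a share under 0.05: real counts were 4975, 4414 and 4165, and the highest others 0, 0 and 1. For lists, 1 and 1 of 10 splits gave as many as the real 11 in KO1 and 13 between the clones, with the highest others at 4 and 10, and 10 splits are again too few. In KO2 3 of 10 splits gave at least the real 8 lists, and another split gave 12, so that count does not exceed what regrouping gives.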
